A study of Arabidopsis thaliana with 28 samples.

How the data were processed

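Total RNA of Arabidopsis thaliana seedlings of the Columbia 0 wild type and the elo3-6 line was measured on 28 two-colour Agilent arrays. Per the labels, seeds were kept for 48 h at 4 °C, seedlings grew for 4 days in darkness at 22 °C, and they then stayed dark or received 1 h of red or far-red light. Per the labels, 200 ng of RNA was labelled with Cy5 or Cy3 together with a mix of 10 spike-in transcripts. The 4 replicates are separate biological experiments per the labels, and each experiment compared its own 6 RNAs on 7 arrays with the same dye orientation in every experiment.

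The authors deposited one scanner file per array, read with Agilent Feature Extraction 10.7.3.1. Per the file headers, spot and background signals are in units of intensity, as mean pixel brightness of the spot and median brightness of its surroundings. Processed signals, also intensity per the file headers, had been background-subtracted, detrended and dye-normalised by that software. The log ratio column is log10 of Cy5 over Cy3 processed signal per the file headers. The deposited value table of the series holds log2 ratios of Cy5 over Cy3, as checked by regression on the log ratios of the same arrays. Its treatment of dim probes is not given in the sources used here.

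Each array held 43803 spots beside 1417 control spots. Mean spot intensities were corrected with normexp (offset 50) and normalised within arrays by loess fitted without the control spots. Over all arrays 582 spots marked as outliers by the scanner software were left out, and 1 spot was saturated. Spots of a probe were averaged, which gave 43603 probes. Of these, 35430 matched 1 locus in the reference table, 34222 by transcript accession and 1208 by the locus in the file, while 482 matched several loci and 7691 matched none. Probes were tested when at least 3 of the 4 RNAs of a group were well above background, which left 29384 probes of 20984 genes. The brightest probe stood for a gene, and 6419 genes had several.

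The gene-specific dye effect was estimated over the 28 arrays and removed, and the levels of the 6 RNAs of an experiment were solved by least squares from its 7 arrays. These RNA levels, 24 per gene, were fitted with limma 3.58.1 in R 4.3.3 with the 6 groups and the experiment as a block, on 15 residual degrees of freedom, with a prior of 2.57 degrees of freedom and a prior SD of 0.0674. The block is part of the study, since each array joined RNAs of 1 experiment. Of 60 pairs of RNAs with the same experiment number, 36 had a correlation across genes above 0.1 after group means were removed (median 0.14). Of 180 pairs with other numbers, 48 did (median -0.04). These correlations used intensities of single channels, in which RNAs on the same array share its spots, so they do not measure the pairing alone. Adjusted p values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05, and 5 genes lacked a value in an experiment. The number of arrays limits the precision.

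Comparisons were elo3-6 against wild type in each light condition, each light against darkness in each genotype, and the interaction of genotype with each light. The lists, 22 in number with 388 genes of which 378 were measured, covered the Elongator complex, photoreceptors and PIFs, light signalling regulators, the clock, chlorophyll biosynthesis, light-harvesting proteins, photosystem subunits with the Calvin cycle, flavonoids, auxin response, growth bHLH and shade-response regulators, cell wall expansion, gibberellin and brassinosteroid metabolism, abscisic acid with cold and drought, salicylate, jasmonate, heat shock, touch and wounding, seed storage, seed reserve mobilisation, root markers, the stomatal lineage and cell division. They were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way.

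The comparisons, tests, lists, the rule for naming genes and most alternatives were fixed before the data were examined. In each comparison the rule named the 6 genes with the largest rise and the 6 with the largest fall among those called with the same sign in 4 of 4 experiments, up to 3 members of each list with the smallest adjusted p, or 2 members where only the list passed, and the Elongator list with HY5, HYH, HFR1, PHYA, PHYB, PIF3, PIF4, LHY, CCA1, PORA and CHS. The list members printed are a subset of those the rule names, chosen after their values were seen. The alternatives were no background subtraction, Agilent processed signals, an offset of 0, median centring, scaling between arrays, other filters on dim probes, no dye effect, array-level fits without and with the slide as a block, only the groups compared, only the direct arrays, single-channel values with and without the replicate block, leaving out each experiment, the mean of a gene's probes, the deposited value table, the estimated correlation and fry, and a stricter threshold for the overlap. Fits without the 2 noisiest arrays of experiment 2, with the scan day as a block, and with a change of 2-fold asked for were chosen after seeing the data.

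The procedure was tested on simulated data with spreads taken from the real arrays. Noise was drawn for each gene on its own, so deviations of an RNA that many genes share were not simulated. For the comparison of elo3-6 with wild type in darkness, on 20844 genes, 26 of 50 genes changed by a log2 of 0.2 were recovered, 33 of 50 at 0.4 and 48 of 50 at 0.8, with 7 false calls among 168. For the red interaction, on as many genes, 8 of 50 were recovered at 0.2, 29 of 50 at 0.4 and 46 of 50 at 0.8, with 7 false calls among 140. Over all comparisons the share of false calls lay between 2.2% (far-red interaction) and 7.6% (elo3-6 against wild type after red light). Tables were read with the package data.table in version 1.17.8, least squares used MASS 7.3.60.0.1, and plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Probes that match no locus were tested only as counts, and control spots were not analysed here.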

Results

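Transcript levels were measured in dark-grown Arabidopsis thaliana seedlings of the Columbia 0 wild type and of elo3-6, an insertion line from the GABI-Kat collection in ELO3. ELO3 encodes the catalytic subunit of Elongator, a histone acetyltransferase complex that accompanies RNA polymerase II and also acts on transfer RNA. Seedlings were 4 days old and were kept in darkness or given 1 h of red or far-red light, so that 2 genotypes and 3 light conditions made 6 groups. Each of 4 biological replicate experiments held 1 RNA of every group, which gave 4 RNAs per group and 24 RNAs in all. The RNAs were hybridised in pairs on 28 Agilent-021169 arrays in 2 colours, 7 arrays per experiment, in a loop that joined the 6 RNAs of an experiment. Between 64.1% and 77.0% of spots were well above background in a channel, and the median spot signal of a channel lay between 241.5 and 734.9. The number of arrays and RNAs, rather than a read depth, limits the precision. Changes are log2 fold changes with the standard error (SE) of the fit, for 4 RNAs per group. The SE uses a common spread of a gene over all 24 RNAs, so it does not show the spread of the RNAs compared. Positions are those of the probes on TAIR10 as the files give them.

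ELO3 (AT5G50320), the disrupted gene, was measured by a probe at chromosome 5, 20481221 to 20481280. Its normalised log2 intensity was 11.88 ± 0.09 (SD, n = 4) in dark wild type and 11.87 ± 0.14 in dark elo3-6. After red light it was 11.80 ± 0.07 in wild type and 11.61 ± 0.05 in elo3-6, and after far-red light 11.91 ± 0.10 and 11.62 ± 0.07. Over the 24 RNAs the values ran from 11.56 to 12.08. The difference of elo3-6 from wild type, fitted on log ratios rather than on these intensities, was 0.01 ± 0.06 in darkness (adjusted p = 0.94), fell by 0.17 ± 0.06 after red light (adjusted p = 0.029) and fell by 0.29 ± 0.06 after far-red light (adjusted p = 9.0e-04). The red call was lost when any of the 4 experiments was left out, with values from -0.20 to -0.14. The position of the insertion relative to this probe is not given in the sources used here, so the probe does not check the genotype labels.

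The first comparison asked which transcripts differ between elo3-6 and wild type in darkness. The highest transcripts in elo3-6 were MRD1 (AT1G53480, chromosome 1, 19963495 to 19963554), at 3.56 ± 0.19 (SE, n = 4) or 11.8-fold with an adjusted p of 3.2e-10, AT5G39180 at 3.00 ± 0.22, and MLS, the malate synthase of the glyoxylate cycle, at 2.86 ± 0.16 (adjusted p = 4.3e-10). AIR1, AT3G53980 and AT4G09530 followed at 2.50 ± 0.19, 2.40 ± 0.23 and 2.38 ± 0.19. The lowest were HOL2, a methyltransferase gene, at -2.57 ± 0.21 (adjusted p = 1.6e-08), AT2G27402 at -1.97 ± 0.11, the laccase gene LAC2 at -1.89 ± 0.19 and AT3G05950 at -1.75 ± 0.39. Also among the 6 lowest were HYH, a bZIP factor close to HY5, at -1.83 ± 0.11 (adjusted p = 7.4e-10), and ELIP1, an early light-inducible thylakoid protein gene, at -1.81 ± 0.13 (adjusted p = 3.7e-09). HY5, the bZIP factor that promotes photomorphogenesis, was lower by a smaller amount, -0.60 ± 0.04 (adjusted p = 1.5e-09). All of these differences had the same sign in 4 of 4 experiments.

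Of the 22 fixed gene lists, 5 passed with camera in the dark mutant, 4 lower and 1 higher, and 1 passed with an estimated correlation. Of 22 measured light signalling regulators, 15 were lower, 1 was higher and 6 did not pass, the same counts when adjusted over the list alone, and their mean was -0.49 (camera adjusted p = 0.0014). This list also passed with an adjusted p = 0.046 with an estimated correlation. Of 26 clock genes, 17 were lower and 1 was higher over all genes tested and also adjusted over the list alone, with RVE4 at -0.74 ± 0.05, ELF3 at -0.41 ± 0.04, LHY at -0.90 ± 0.17 and CCA1 at -0.41 ± 0.13, the last lost without replicate experiment 3 (adjusted p = 0.064). The clock list had a mean of -0.32 and an adjusted p of 7.8e-04, against an adjusted p = 0.42 with an estimated correlation. Of 38 auxin response genes 23 were lower and 5 higher (the same adjusted over the list alone), among them YUC8, an auxin biosynthesis gene, at -0.67 ± 0.06. Their mean was -0.24 (adjusted p = 0.0084, and adjusted p = 0.99 with an estimated correlation). Of 14 cell division genes 9 were lower and 2 higher, or 10 and 2 adjusted over the list alone, including the mitotic kinase gene AUR1 at -0.70 ± 0.05, the cytokinesis syntaxin gene KNOLLE at -0.82 ± 0.07 and CDKB2;1 at -0.999 ± 0.10. Their mean was -0.34 with an adjusted p of 0.017, and adjusted p = 0.78 with an estimated correlation. The Elongator list moved the other way, with 5 of 7 members higher, 5 also adjusted over the list alone. The mean over the list was 0.17 (adjusted p = 0.049, and adjusted p = 0.61 with an estimated correlation). ELO2 was higher by 0.29 ± 0.03, ELP2 by 0.31 ± 0.05, ELP5 by 0.25 ± 0.03, ELO1 by 0.17 ± 0.04 and ELP6 by 0.15 ± 0.05, while DRL1 stood at 0.05 ± 0.02 (adjusted p = 0.067). Without replicate experiment 3 the Elongator list no longer passed (adjusted p = 0.10).

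Single members of lists that did not pass as a whole also differed in darkness. The brassinosteroid biosynthesis genes CPD and DWF4 were lower by -0.63 ± 0.04 and -0.64 ± 0.06, and the growth-promoting bHLH gene PIF4 was lower by -0.68 ± 0.06, whereas PIF3 was higher by 0.37 ± 0.09. The gluconeogenic PCK1 was higher by 0.91 ± 0.06, the peroxisomal PMDH1 by 0.50 ± 0.03, the jasmonate biosynthesis gene OPR3 by 0.60 ± 0.04 and the dehydrin gene LTI30 by 1.297 ± 0.18. Among photosynthesis genes, RBCS1A, LHCB2.1 and LHCB3 were higher by 0.97 ± 0.15, 0.66 ± 0.15 and 0.69 ± 0.17, and RBCS1B and GUN4 were lower by -1.004 ± 0.20 and -0.85 ± 0.13. The seed storage genes SESA5 and SESA3 were higher by 1.82 ± 0.42 and 1.44 ± 0.24. PHYB (-0.07 ± 0.04, adjusted p = 0.13) and CHS (0.27 ± 0.29, adjusted p = 0.42) did not pass. In all, limma called 13267 of 20984 genes in darkness, 6651 higher and 6616 lower, with a median absolute change of 1.22-fold, and 359 of them changed by 2-fold or more. Median centring in place of loess raised the share of higher calls from 50.1% to 60.6%.

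After red light, elo3-6 differed from wild type in many of the same transcripts. MRD1 was higher by 3.65 ± 0.19 or 12.6-fold (adjusted p = 1.8e-10), AT5G39180 by 3.15 ± 0.22, AIR1 by 2.67 ± 0.19, the fatty acid desaturase gene ADS4 by 2.61 ± 0.15, AT3G53980 by 2.59 ± 0.23 and MLS by 2.55 ± 0.16. HOL2 was lower by -2.57 ± 0.21, AT3G05950 by -2.37 ± 0.39 and CGA1, a GATA factor of chloroplast development, by -2.24 ± 0.18 (adjusted p = 1.3e-08). The methionine sulfoxide reductase gene MSRB6 stood at -2.08 ± 0.11, AT2G27402 at -2.05 ± 0.11 and AT4G37220 at -1.97 ± 0.37. HYH remained lower at -1.35 ± 0.11 and HY5 at -0.19 ± 0.04 (adjusted p = 3.3e-04). XTH15, a xyloglucan-modifying enzyme gene, was higher by 1.16 ± 0.10, and the heat shock gene HSP101 was lower by -1.01 ± 0.12.

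The lists that differed after red light were all lower in elo3-6. Of 26 clock genes 21 were lower and none higher, also adjusted over the list alone, with RVE4 and RVE8 each at -0.70 (SE 0.05 and 0.07), LHY at -0.77 ± 0.17 and CCA1 at -0.57 ± 0.13. The clock mean was -0.35 (adjusted p = 1.3e-04, and adjusted p = 0.28 with an estimated correlation). Light signalling regulators had 14 lower and 2 higher of 22, also adjusted over the list alone, BBX25 among them at -1.09 ± 0.11. The mean change was -0.31 (adjusted p = 0.027, and adjusted p = 0.28 with an estimated correlation). Of 38 auxin response genes 26 were lower and 4 higher, also adjusted over the list alone, including IAA14 at -0.70 ± 0.08. Their average was -0.29 (adjusted p = 7.0e-04, and adjusted p = 0.87 with an estimated correlation). Of 14 cell division genes 10 were lower and none higher, also adjusted over the list alone, with AUR1 at -0.74 ± 0.05. On average they stood at -0.40 (adjusted p = 0.0021, and adjusted p = 0.64 with an estimated correlation). Light-harvesting protein genes had 11 of 21 lower and none higher, also adjusted over the list alone, with LHCB2.3 at -1.50 ± 0.17 and LHCB7 at -0.75 ± 0.08. Their mean was -0.46 (adjusted p = 0.027, and adjusted p = 0.87 with an estimated correlation), and the call was lost without replicate experiment 1 (adjusted p = 0.11) or 4 (adjusted p = 0.058). Among other photosynthesis genes RBCS1B stood at -1.69 ± 0.20 and GUN4 at -1.01 ± 0.13. CHS, the first enzyme gene of flavonoid synthesis, was lower by -0.77 ± 0.29 (adjusted p = 0.026), a call that leaving out experiment 1, 3 or 4 ended (adjusted p = 0.074, 0.052 and 0.080). In total 13166 genes differed, 6518 higher and 6648 lower, and 368 changed by 2-fold or more. Median centring turned this balance, with 6032 higher and 4337 lower, and the share of higher calls moved from 49.5% to 58.2%.

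After far-red light MRD1 was again the highest transcript in elo3-6, at 3.69 ± 0.19 or 12.9-fold (adjusted p = 2.3e-10), followed by AT5G39180 at 2.78 ± 0.22, SESA5 at 2.77 ± 0.42, MLS at 2.48 ± 0.16, AIR1 at 2.44 ± 0.19 and AT3G53980 at 2.42 ± 0.23. HOL2 was lower by -2.37 ± 0.21, AT1G26761 by -2.14 ± 0.15 and LHCB1.1, which encodes a major light-harvesting protein of photosystem II, by -2.11 ± 0.38 (adjusted p = 1.2e-04). AT2G27402, MSRB6 and CGA1 stood at -2.07 ± 0.11, -2.02 ± 0.11 and -1.99 ± 0.18. ELIP2 was lower by -1.64 ± 0.16, HYH by -1.46 ± 0.11 and BBX25 by -1.35 ± 0.11, and HY5 did not pass (-0.08 ± 0.04, adjusted p = 0.10). The glyoxylate cycle gene ICL was higher by 1.61 ± 0.13.

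Light-harvesting, photosystem and flavonoid lists were lower in far-red-treated elo3-6, and the chlorophyll list, with a mean of -0.22, did not pass (adjusted p = 0.11). Light-harvesting protein genes had 13 of 21 lower and none higher, also adjusted over the list alone, with LHCB2.3 at -1.39 ± 0.17 and LHCB7 at -0.80 ± 0.08. Their average change was -0.58 (adjusted p = 0.0016, and adjusted p = 0.83 with an estimated correlation). Photosystem and Calvin cycle genes had 23 of 39 lower and 1 higher, also adjusted over the list alone, including RBCS1B at -1.76 ± 0.20 and PSAN at -0.77 ± 0.09. Their mean was -0.35 (adjusted p = 0.0043, and adjusted p = 0.84 with an estimated correlation), and without replicate experiment 1 the call was lost (adjusted p = 0.077). The means of experiments 1 to 4 were -0.69, -0.06, -0.69 and 0.04. Flavonoid pathway genes had 15 of 25 lower and 2 higher, also adjusted over the list alone, with 4CL3 at -1.37 ± 0.14, 4CL1 at -0.51 ± 0.04 and CHS at -1.27 ± 0.29. The average change was -0.38 (adjusted p = 0.0043, and adjusted p = 0.49 with an estimated correlation). The clock list, with 18 of 26 lower, had a mean of -0.33 (adjusted p = 3.8e-04, and adjusted p = 0.38 with an estimated correlation), LHY standing at -1.05 ± 0.17 and CCA1 at -0.69 ± 0.13. Cell division genes had 10 of 14 lower and a mean of -0.41 (adjusted p = 3.8e-04, and adjusted p = 0.48 with an estimated correlation). Both lists gave the same counts adjusted over the list alone. Light signalling regulators had 11 lower and 4 higher of 22, also adjusted over the list alone. Their mean was -0.35 (adjusted p = 0.021, and adjusted p = 0.38 with an estimated correlation). Auxin response genes had 21 lower and 4 higher of 38, or 22 and 4 adjusted over the list alone. These genes averaged -0.19 (adjusted p = 0.015, and adjusted p = 0.84 with an estimated correlation). The auxin mean was -0.12 without replicate experiment 4, where the call was lost (adjusted p = 0.14), and -0.28 without experiment 1. The Elongator list was higher, with 6 of 7 members higher and ELO3 lower, also adjusted over the list alone. Together they averaged 0.14 (adjusted p = 0.049, and adjusted p = 0.49 with an estimated correlation), a call lost without replicate experiment 3 (adjusted p = 0.10) or 4 (adjusted p = 0.051).

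Seed storage and late embryogenesis genes were higher in far-red-treated elo3-6, with 8 of 12 higher, 9 adjusted over the list alone. The list averaged 1.12 (adjusted p = 0.024, and adjusted p = 0.83 with an estimated correlation). CRA1, a 12S globulin gene, stood at 2.26 ± 0.43 and SESA3, a 2S albumin gene, at 1.46 ± 0.24. Replicate experiment 1 stood apart here: its list mean was 2.55, against 0.49 to 0.80 in the other experiments, and without it the list mean was 0.64 and CRA1 1.28, both still past the threshold. Over all genes 12638 differed after far-red light, 6492 higher and 6146 lower, and 328 changed by 2-fold or more.

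The next comparisons asked which transcripts respond to 1 h of light. In wild type under red light the B-box gene BBX32 rose by 5.83 ± 0.08 (SE, n = 4) or 56.9-fold (adjusted p = 1.6e-19), the ABC transporter gene ABCI21 by 5.08 ± 0.07, AT3G56290 by 4.94 ± 0.05, the plastid sigma factor gene SIGE by 4.84 ± 0.09, AT1G48100 by 4.80 ± 0.07 and BBX31 by 4.71 ± 0.09. PIL1, a phytochrome-interacting-factor-like bHLH gene known from shade responses, fell by 3.56 ± 0.08 or 11.8-fold (adjusted p = 2.7e-16), BBX23 fell by 3.54 ± 0.16, the small peptide gene RTFL21 fell by 3.504 ± 0.05 and AT5G57760 fell by 3.42 ± 0.15. GRF7 fell by 3.07 ± 0.12 and the shade-responsive homeobox gene ATHB2 fell by 2.66 ± 0.07. HY5 rose by 3.07 ± 0.04 or 8.40-fold (adjusted p = 7.2e-20), HYH by 2.15 ± 0.11, GA2OX1, a gibberellin-inactivating enzyme gene, by 4.53 ± 0.14, the heat shock factor gene HSFA2 by 2.56 ± 0.13 and the expansin gene EXPA1 by 2.25 ± 0.12. All had the same sign in 4 of 4 experiments.

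Clock genes responded upward to red light in wild type, with 22 of 26 risen and none fallen, also adjusted over the list alone, PRR9 by 3.78 ± 0.10, LNK1 by 2.74 ± 0.07, GI by 2.095 ± 0.05, CCA1 by 2.05 ± 0.13 and LHY by 1.195 ± 0.17. The list mean was 1.296 (adjusted p = 1.9e-19, and adjusted p = 0.0026 with an estimated correlation). Of 22 light signalling regulators 12 rose and 6 fell, also adjusted over the list alone, with RUP2 up by 3.316 ± 0.07. Their mean change was 0.98 (adjusted p = 3.7e-04, and adjusted p = 0.022 with an estimated correlation). Of 25 flavonoid pathway genes 17 rose, 19 adjusted over the list alone, including UGT78D2 by 3.68 ± 0.07, F3H by 3.38 ± 0.11 and CHS by 1.48 ± 0.29. The average of the list was 0.96 (adjusted p = 9.7e-11, and adjusted p = 0.024 with an estimated correlation). Growth bHLH and shade-response regulators fell in 11 of 16 cases and rose in 1, or 12 and 1 adjusted over the list alone, among them HAT3 (-1.78 ± 0.07) and ATHB4 (-2.01 ± 0.09). The average change was -0.94 (adjusted p = 1.2e-08, and adjusted p = 0.029 with an estimated correlation).

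Light-harvesting protein genes rose in 17 of 21 cases, also adjusted over the list alone, LHCA1 by 2.38 ± 0.17 and LHCB7 by 1.86 ± 0.08. Their mean was 1.27 (adjusted p = 9.7e-11, and adjusted p = 0.37 with an estimated correlation). Photosystem and Calvin cycle genes rose in 23 of 39 cases, 25 adjusted over the list alone, PSBS by 1.55 ± 0.14, and had a mean of 0.51 (adjusted p = 6.9e-07, and adjusted p = 0.77 with an estimated correlation). Auxin response genes fell in 22 of 38 cases and rose in 5, or 23 and 6 adjusted over the list alone, IAA29 falling by 2.61 ± 0.10. The mean over the list was -0.41 (adjusted p = 6.2e-06, and adjusted p = 0.63 with an estimated correlation). Abscisic acid and cold or drought response genes rose in 6 of 16 cases, also adjusted over the list alone, ABF3 by 1.25 ± 0.06. The mean change was 0.34 (adjusted p = 0.021, and adjusted p = 0.80 with an estimated correlation). The chlorophyll list did not pass, although CAO and CHLH rose by 1.61 ± 0.08 and 1.62 ± 0.13. PORA, a protochlorophyllide reductase gene, fell by 0.96 ± 0.17. PHYA, the far-red photoreceptor gene, fell by 0.70 ± 0.05 and PIF4 rose by 0.65 ± 0.06. PHYB (0.05 ± 0.04), PIF3 (-0.11 ± 0.09) and HFR1 (0.08 ± 0.07) did not pass. Of all genes 7259 responded, 3560 up and 3699 down, with 462 up and 123 down by 2-fold or more. With Agilent processed signals the share of upward calls was 35.5% in place of 49.0%.

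Far-red light changed largely the same transcripts in wild type. BBX32 rose by 5.83 ± 0.08 or 56.7-fold (adjusted p = 2.4e-19), AT3G56290 by 4.72 ± 0.05, the MYB-like gene ASG4 by 4.65 ± 0.18, ABCI21 by 4.62 ± 0.07, SIGE by 4.60 ± 0.09 and AT1G48100 by 4.52 ± 0.07. BBX23 fell by 2.67 ± 0.16, AT5G57760 fell by 2.44 ± 0.15, RTFL21 fell by 2.41 ± 0.05, EXO fell by 2.41 ± 0.15, PIL1 fell by 2.33 ± 0.08 and EXL5 fell by 2.29 ± 0.14. HY5 rose by 2.68 ± 0.04 and HYH by 1.97 ± 0.11. PHYA fell by 0.48 ± 0.05, PORA fell by 0.58 ± 0.17 and HFR1 rose by 0.26 ± 0.07 (adjusted p = 0.0040). The PORA call was lost without replicate experiment 2 (adjusted p = 0.096) or 4 (adjusted p = 0.082), and the HFR1 call without experiment 2 (adjusted p = 0.064).

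Clock genes rose in 22 of 26 cases under far-red light and fell in 1, or 23 and 1 adjusted over the list alone, LNK1 by 2.56 ± 0.07, RVE1 by 2.204 ± 0.06 and GI by 2.04 ± 0.05. Their average was 1.21 (adjusted p = 4.3e-19, and adjusted p = 0.0029 with an estimated correlation). Light signalling regulators had 13 risen and 7 fallen of 22, also adjusted over the list alone. On average they stood at 1.01 (adjusted p = 3.1e-04, and adjusted p = 0.019 with an estimated correlation). Flavonoid genes rose in 16 of 25 cases, 17 adjusted over the list alone, UGT78D2 by 3.68 ± 0.07, F3H by 3.45 ± 0.11 and CHS by 1.69 ± 0.29. Their average change was 0.96 (adjusted p = 3.4e-10, and adjusted p = 0.032 with an estimated correlation). Light-harvesting protein genes rose in 19 of 21 cases, also adjusted over the list alone, LHCB2.2 by 3.08 ± 0.21 and LHCB2.1 by 2.62 ± 0.15. The list mean was 1.41 (adjusted p = 1.1e-12, and adjusted p = 0.26 with an estimated correlation). Photosystem and Calvin cycle genes rose in 30 of 39 cases, also adjusted over the list alone. Their mean was 0.65 (adjusted p = 2.8e-10, and adjusted p = 0.66 with an estimated correlation). Abscisic acid and cold or drought response genes rose in 8 of 16 cases, also adjusted over the list alone, ABI1 by 1.01 ± 0.09. These genes averaged 0.52 (adjusted p = 3.9e-04, and adjusted p = 0.66 with an estimated correlation). Growth bHLH and shade-response regulators fell in 12 of 16 cases and rose in 1, also adjusted over the list alone, ATHB2 falling by 2.18 ± 0.07. Together they averaged -0.71 (adjusted p = 2.0e-06, and adjusted p = 0.081 with an estimated correlation). Chlorophyll biosynthesis genes rose in 8 of 23 cases and fell in 3, or 9 and 3 adjusted over the list alone, CAO by 1.67 ± 0.08. The list averaged 0.33 (adjusted p = 0.0088, and adjusted p = 0.86 with an estimated correlation). Without replicate experiment 3 the chlorophyll mean was 0.19 and the call was lost (adjusted p = 0.21). Auxin response genes fell in 18 of 38 cases and rose in 8, or 19 and 8 adjusted over the list alone. Their mean change was -0.16 (adjusted p = 0.033, and adjusted p = 0.87 with an estimated correlation), a call lost without replicate experiment 1 (mean -0.08, adjusted p = 0.15) or 3 (adjusted p = 0.21).

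Over all genes 7623 responded to far-red light in wild type, 3708 up and 3915 down, with 466 up and 74 down by 2-fold or more. The wild-type far-red RNAs varied more between experiments than most others, up to an SD of 0.155 across genes for experiment 4, and a spread estimated from the compared groups alone left 3744 calls. Median centring left 4610, only the direct arrays 4736, and Agilent processed signals moved the share of upward calls from 48.6% to 34.2%.

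The red and far-red responses of wild type shared 5336 genes changed in the same direction, 2686 up and 2650 down, and 22 changed in opposite directions. Independent lists of these lengths would share 629.1 and 690.1. Across genes the log2 changes had a correlation of 0.93 and a covariance of 0.128, although genes are not independent replicates. Both responses were taken against the same dark RNAs. Simulated unchanged groups against simulated dark RNAs gave a mean of 0 shared genes, a correlation of 0.50 and a covariance of 0.0036. The observed covariance exceeded this value by 0.125. The noise was drawn for each gene on its own, so it holds no deviation that many genes of the real dark RNAs share. With the red response from experiments 1 and 2 and the far-red response from 3 and 4, 2276 genes were shared and the correlation was 0.85. With the experiments exchanged 2445 genes were shared. These responses had no dark RNA in common, and their covariances were 0.122 and 0.126.

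In elo3-6 under red light BBX32 rose by 5.56 ± 0.08 or 47.2-fold (adjusted p = 2.7e-19), ABCI21 by 4.76 ± 0.07, SIGE by 4.68 ± 0.09, ELIP1 by 4.66 ± 0.13, GA2OX1 by 4.61 ± 0.14 and BBX31 by 4.52 ± 0.09. PIL1 fell by 3.175 ± 0.08, RTFL21 fell by 3.1 ± 0.05, IAA29 fell by 2.89 ± 0.10, BBX23 fell by 2.83 ± 0.16, GRF7 fell by 2.80 ± 0.12 and AT5G57760 fell by 2.77 ± 0.15. HY5 rose by 3.48 ± 0.04 or 11.2-fold, HYH by 2.63 ± 0.11 and SPA1, a repressor that acts with COP1, by 2.84 ± 0.06. CHS did not pass (0.44 ± 0.29, adjusted p = 0.29). PORA fell by 0.69 ± 0.17, a call lost without replicate experiment 4 (adjusted p = 0.078).

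Clock genes rose in 22 of 26 cases in red-treated elo3-6, also adjusted over the list alone, LNK1 by 2.57 ± 0.07, CCA1 by 1.88 ± 0.13 and LHY by 1.32 ± 0.17. The average of the list was 1.27 (adjusted p = 5.1e-23, and adjusted p = 0.0011 with an estimated correlation). Light signalling regulators had 13 risen and 6 fallen of 22. The average change was 1.16 (adjusted p = 1.2e-05, and adjusted p = 0.0046 with an estimated correlation), and flavonoid genes had 17 risen of 25, UGT78D2 by 3.52 ± 0.07. Their mean was 0.79 (adjusted p = 7.7e-10, and adjusted p = 0.026 with an estimated correlation). Both counts were the same adjusted over the list alone. Growth bHLH and shade-response regulators fell in 13 of 16 cases, 13 also adjusted over the list alone with 1 risen, ATHB2 falling by 2.57 ± 0.07. The mean over the list was -0.99 (adjusted p = 1.3e-10, and adjusted p = 0.015 with an estimated correlation). Light-harvesting protein genes rose in 12 of 21 cases, also adjusted over the list alone, LHCB2.1 by 1.28 ± 0.15 and LHCB7 by 1.18 ± 0.08. The mean change was 0.73 (adjusted p = 1.1e-06, and adjusted p = 0.56 with an estimated correlation). Members of the photosystem and Calvin cycle list rose in 9 of 39 cases, also adjusted over the list alone. Their average was 0.30 (adjusted p = 7.8e-04, and adjusted p = 0.79 with an estimated correlation), or 0.20 without replicate experiment 3. Auxin response genes fell in 23 of 38 cases and rose in 5, or 25 and 5 adjusted over the list alone. On average they stood at -0.46 (adjusted p = 6.1e-08, and adjusted p = 0.56 with an estimated correlation). Heat shock genes rose in 4 of 10 cases, HSFA2 by 2.27 ± 0.13. Their average change was 0.66 (adjusted p = 0.0049, and adjusted p = 0.64 with an estimated correlation), and abscisic acid and cold or drought response genes rose in 5 of 16. The list mean was 0.38 (adjusted p = 0.0045, and adjusted p = 0.64 with an estimated correlation). Both lists kept these counts adjusted over the list alone. In total 6247 genes responded, 3151 up and 3096 down, with 378 up and 94 down by 2-fold or more. Median centring left 3953 calls, and Agilent processed signals moved the share of upward calls from 50.4% to 35.3%.

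Far-red light in elo3-6 raised BBX32 by 5.50 ± 0.08 or 45.4-fold (adjusted p = 4.3e-19), ELIP1 by 4.72 ± 0.13, ASG4 by 4.68 ± 0.18, SIGE by 4.36 ± 0.09, ABCI21 by 4.34 ± 0.07 and BBX31 by 4.08 ± 0.09. IAA29 fell by 2.54 ± 0.10, ATHB2 fell by 2.08 ± 0.07, PIL1 fell by 2.06 ± 0.08, XTH16 fell by 1.98 ± 0.17, RTFL21 fell by 1.98 ± 0.05 and BBX23 fell by 1.94 ± 0.16. HY5 rose by 3.21 ± 0.04 and HYH by 2.33 ± 0.11, while CHS did not pass (0.15 ± 0.29, adjusted p = 0.74). PORA fell by 0.49 ± 0.17, a call lost without replicate experiment 1 (adjusted p = 0.14) or 4 (adjusted p = 0.13).

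Clock genes rose in 24 of 26 cases in far-red-treated elo3-6, 25 adjusted over the list alone, LNK1 by 2.35 ± 0.07 and CCA1 by 1.54 ± 0.13. Their mean was 1.21 (adjusted p = 3.3e-24, and adjusted p = 8.4e-04 with an estimated correlation). Light signalling regulators had 13 risen and 6 fallen of 22, also adjusted over the list alone. These genes averaged 1.15 (adjusted p = 6.8e-06, and adjusted p = 0.0036 with an estimated correlation). Light-harvesting protein genes rose in 12 of 21 cases, 15 adjusted over the list alone, LHCB2.1 by 1.27 ± 0.15 and LHCB7 by 1.19 ± 0.08. Together they averaged 0.76 (adjusted p = 4.8e-07, and adjusted p = 0.40 with an estimated correlation). Photosystem subunit and Calvin cycle genes rose in 10 of 39 cases, 9 adjusted over the list alone. The list averaged 0.33 (adjusted p = 3.2e-04, and adjusted p = 0.71 with an estimated correlation). Flavonoid genes had 14 risen and 1 fallen of 25, also adjusted over the list alone, UGT78D2 rising by 3.28 ± 0.07. Their mean change was 0.65 (adjusted p = 3.1e-06, and adjusted p = 0.12 with an estimated correlation). Growth bHLH and shade-response regulators fell in 11 of 16 cases, or 12 with 1 risen adjusted over the list alone. The average of the list was -0.73 (adjusted p = 2.2e-07, and adjusted p = 0.057 with an estimated correlation).

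Lists for abscisic acid, heat shock, touch and photoreceptors also rose in far-red-treated elo3-6. The jasmonate (camera adjusted p = 0.089) and salicylate lists (camera adjusted p = 0.37) did not pass. Abscisic acid and cold or drought response genes rose in 8 of 16 cases, 9 adjusted over the list alone. The average change was 0.68 (adjusted p = 6.8e-06, and adjusted p = 0.40 with an estimated correlation). Heat shock genes rose in 6 of 10 cases, also adjusted over the list alone, HSFA2 by 2.23 ± 0.13. Their mean was 0.69 (adjusted p = 7.2e-04, and adjusted p = 0.40 with an estimated correlation). Touch and wounding genes, fixed as a sign of handling, rose in 6 of 10 cases, or 7 with 1 fallen adjusted over the list alone, ZAT12 by 0.89 ± 0.07 and ZAT10 by 0.95 ± 0.11. The mean over the list was 0.30 (adjusted p = 0.014, and adjusted p = 0.40 with an estimated correlation), a call lost without replicate experiment 3 (adjusted p = 0.053). Photoreceptor and PIF genes had 6 risen and 1 fallen of 12, or 7 and 1 adjusted over the list alone. The mean change was 0.20 (adjusted p = 0.012, and adjusted p = 0.40 with an estimated correlation). In total 6867 genes responded, 3581 up and 3286 down, with 363 up and 44 down by 2-fold or more. Median centring left 4263 calls and moved the share of upward calls from 52.2% to 39.2%, Agilent processed signals moved it to 37.2%, and leaving out replicate experiment 2 left 4337 calls.

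**Figure D1:**
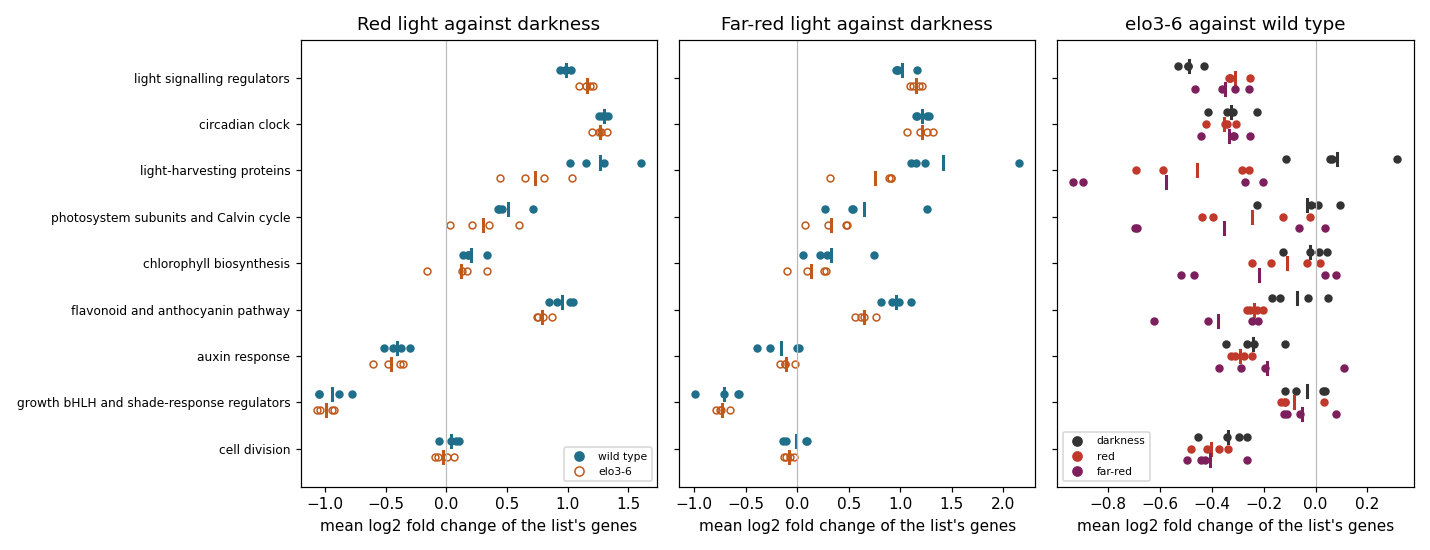
Mean log2 change of 9 gene lists (horizontal axis) in the comparisons named in the 3 panels, with a point for each of the 4 replicate experiments and a bar for their mean. Clock genes rose under red light in wild type by 1.296 and in elo3-6 by 1.27, while light-harvesting genes rose by 1.27 and 0.73.

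The last comparisons asked whether the response to light differs between the genotypes, tested as the interaction of genotype and light, in which a negative value means a smaller rise or a larger fall in elo3-6. Under red light the response of AT1G48100 was smaller in elo3-6 by -1.21 ± 0.10 (SE, n = 4, adjusted p = 1.7e-05), a result that passed without each of the 4 experiments in turn. BBX16 stood at -1.77 ± 0.36 (adjusted p = 0.030), AT2G27420 at -1.33 ± 0.21, MSRB6 at -1.25 ± 0.16, CGA1 at -1.20 ± 0.25 (adjusted p = 0.035) and CXE13, a carboxylesterase gene, at -1.13 ± 0.17. In the other direction stood XTH15 at 1.06 ± 0.14 (adjusted p = 8.8e-04), whose fall was smaller in the mutant, AT4G25250 at 0.97 ± 0.15, AT3G15570 at 0.89 ± 0.19, ELIP1 at 0.88 ± 0.18, the bHLH gene HEC1 at 0.86 ± 0.17 and XTH33 at 0.84 ± 0.18. The HY5 response was larger in elo3-6 by 0.41 ± 0.05 (adjusted p = 0.0010), that of RUP1 by 0.59 ± 0.11 and that of SPA1 by 0.40 ± 0.08. HY5 and ELIP1 began lower in dark elo3-6, and their mean levels after red light were not above those of wild type. HYH (0.48 ± 0.15, adjusted p = 0.25) and CHS (-1.04 ± 0.40, adjusted p = 0.44) did not pass. Of the 19 named genes called here, 18 lost the call when at least 1 experiment was left out, and CGA1 turned to 0.13 (adjusted p = 0.99) with Agilent processed signals.

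Light-harvesting protein genes had the largest list shift in the red interaction, a mean of -0.54 in which 1 of 21 genes passed over all genes, LHCB7 at -0.68 ± 0.11, and 9 adjusted over the list alone (adjusted p = 1.8e-13, and adjusted p = 0.48 with an estimated correlation). Light signalling regulators shifted up by a mean of 0.18, with 4 of 22 up, or 7 up and 3 down adjusted over the list alone (adjusted p = 6.2e-05, and adjusted p = 0.013 with an estimated correlation). Genes of photosystems and the Calvin cycle had a mean of -0.21 with none of 39 called, FBA1 standing at -0.98 ± 0.24 (adjusted p = 0.078), and 1 lower adjusted over the list alone (adjusted p = 4.2e-05, and adjusted p = 0.93 with an estimated correlation). Flavonoid genes had a mean of -0.17 with 2 lower and 1 higher of 25, or 7 and 3 adjusted over the list alone, UGT89C1 at -0.70 ± 0.12, 4CL3 at -0.997 ± 0.20 and MYB12 at 0.59 ± 0.12 (list adjusted p = 0.046, and adjusted p = 0.93 with an estimated correlation). The flavonoid call was lost without replicate experiment 1 (adjusted p = 0.11) or 2 (adjusted p = 0.14). Touch and wounding genes had a mean of 0.19 with none of 10 called and 2 higher adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.48 with an estimated correlation). Over all genes 124 passed, 44 up and 80 down, 7 of them by 2-fold or more, against 120 with and 69 without the replicate block on single-channel values, 39 with median centring and 30 with scaling between arrays. Leaving out an experiment gave 65, 9, 33 and 23 calls for experiments 1 to 4.

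Under far-red light AT2G27420 stood at -1.76 ± 0.21 (adjusted p = 2.8e-04), LHCB2.2 (chromosome 2, 1799429 to 1799485) at -1.60 ± 0.30 (adjusted p = 0.011), AT1G60590 at -1.49 ± 0.30, the thiolase gene KAT5 at -1.49 ± 0.33, AT5G42760 at -1.47 ± 0.16 (adjusted p = 8.0e-05) and CXE13 at -1.44 ± 0.17. In the other direction stood AT3G51750 at 1.13 ± 0.23, the abscisic-acid-induced phosphatase gene HAI3 at 1.12 ± 0.20, AT1G70640 at 1.09 ± 0.21, MAPKKK18 at 1.08 ± 0.26, EXO at 1.01 ± 0.21 and CBF4 at 0.98 ± 0.20. The HY5 response was larger in elo3-6 by 0.53 ± 0.05 (adjusted p = 7.9e-05), from a lower level in darkness to a mean level not above that of wild type. SPA1 stood at 0.38 ± 0.08, XTH15 at 0.88 ± 0.14 and RUP2 at -0.43 ± 0.09, while HYH (0.37 ± 0.15, adjusted p = 0.30) and CHS (-1.54 ± 0.40, adjusted p = 0.066) did not pass. Of the 24 named genes called, 18 lost the call when at least 1 experiment was left out. The ones that passed each time were AT2G27420, AT5G42760, CXE13, HY5, LHCB2.1 and UGT89C1.

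Light-harvesting protein genes again shifted most, with 5 of 21 lower, 13 adjusted over the list alone. Their average was -0.66 (adjusted p = 5.5e-14, and adjusted p = 0.25 with an estimated correlation). LHCB2.1 stood at -1.35 ± 0.21, LHCB3 at -1.29 ± 0.24 and LHCB7 at -0.73 ± 0.11, and the list means of experiments 1 to 4 were -0.79, -0.33, -1.25 and -0.27. Flavonoid genes had 5 lower of 25, or 9 lower and 2 higher adjusted over the list alone, with 4CL3 at -1.27 ± 0.20, UGT78D1 at -1.19 ± 0.20 and UGT89C1 at -0.86 ± 0.12. On average they stood at -0.31 (adjusted p = 3.4e-05, and adjusted p = 0.25 with an estimated correlation). The photosystem and Calvin cycle list had 1 lower of 39, FBA1 at -1.06 ± 0.24, also adjusted over the list alone. Its average change was -0.32 (adjusted p = 1.8e-09, and adjusted p = 0.78 with an estimated correlation), or -0.16 without replicate experiment 3, and in experiments 1 to 4 it was -0.46, -0.05, -0.79 and 0.03. Chlorophyll biosynthesis genes had 1 lower of 23, HEMA1 at -0.59 ± 0.12, and 3 adjusted over the list alone. The list mean was -0.20 (adjusted p = 1.1e-04, and adjusted p = 0.78 with an estimated correlation), or -0.13 and -0.10 without experiments 1 and 3. It had the same sign in 2 of 4 experiments, with means of -0.39, 0.06, -0.48 and 0.03. Light signalling regulators had 3 higher and 2 lower of 22, or 9 and 4 adjusted over the list alone. Their mean was 0.14 (adjusted p = 0.0011, and adjusted p = 0.070 with an estimated correlation). Touch and wounding genes had none of 10 called and 5 higher adjusted over the list alone, TCH4 standing at 0.84 ± 0.26 and TCH3 at 0.46 ± 0.13. These genes averaged 0.30 (adjusted p = 1.1e-04, and adjusted p = 0.25 with an estimated correlation). Seed reserve mobilisation genes had none of 9 called, also adjusted over the list alone. Together they averaged -0.12 (adjusted p = 0.044, and adjusted p = 0.25 with an estimated correlation), a call lost without experiment 1, 2 or 4 (adjusted p = 0.19, 0.056 and 0.11). Over all genes 333 passed, 133 up and 200 down, 26 of them by 2-fold or more, against 278 with and 173 without the replicate block on single-channel values, 13 with the spread of the compared groups alone and 49 with scaling between arrays. Median centring left 125, of which 16.0% were up in place of 39.9%, and leaving out an experiment gave 158, 38, 59 and 134 calls for experiments 1 to 4.

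**Figure D2:**
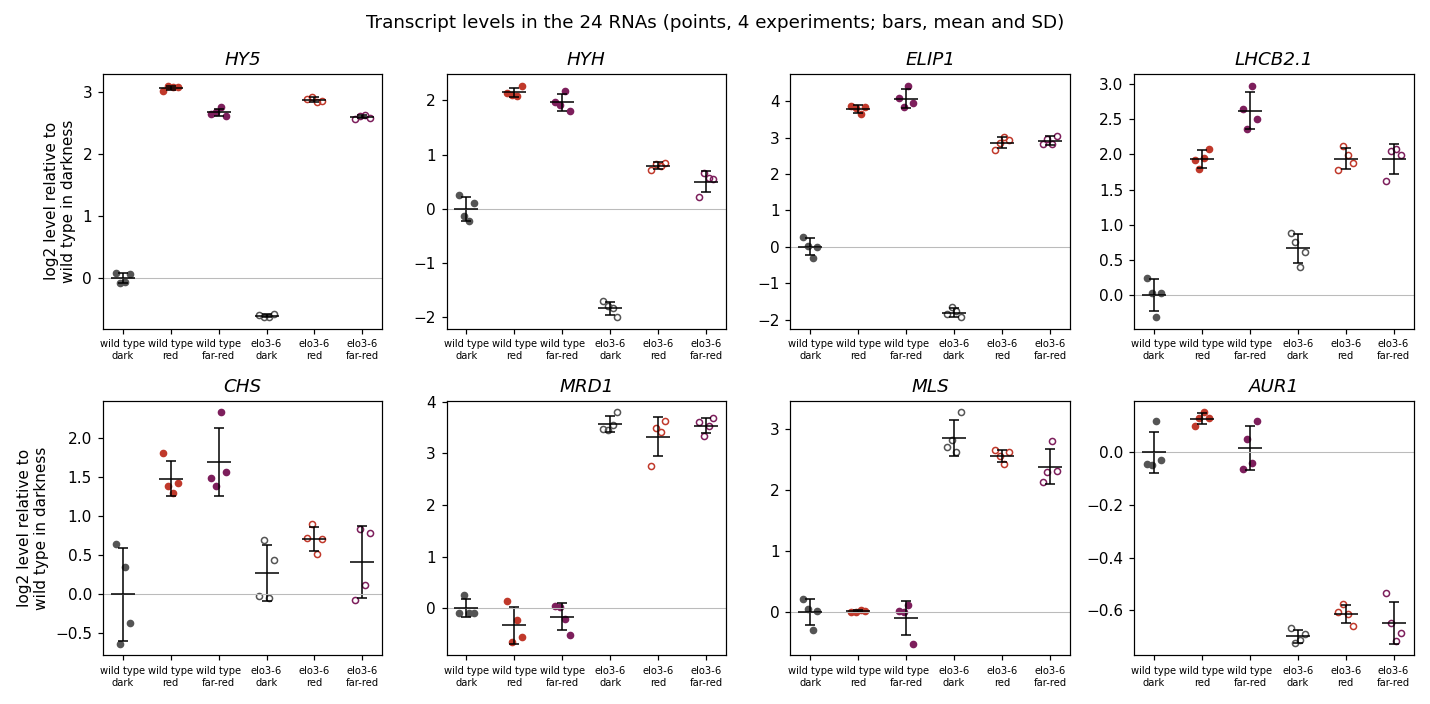
Log2 level of 8 genes relative to the mean of dark wild type (vertical axis) in the 6 groups, with a point for each of 4 experiments and bars for the mean and SD. HY5 rose under red light by 3.07 in wild type and by 3.48 in elo3-6, and LHCB2.1 rose under far-red light by 2.62 and 1.27.

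The arrays lay on 7 slides and were scanned on 2 days, with 16 arrays on the first day and 12 on the second, and each day held all 6 groups. Within both days, 67 of 67 list results kept the sign they had over all arrays, as did 584 of 584 called results of the genes that the naming rule picks, not all of which are printed here. The calls came from these same arrays, which favours agreement in sign. Of all genes called in a comparison, 99.71% to 100% kept their sign on a day. The sizes differed between the days, of which the first held experiments 1 and 2 with 2 arrays of experiment 3, and the second the rest. The red interaction was -0.07 and -0.49 for the photosystem list and -0.36 and -0.79 for the light-harvesting list on the first and second day, and seed storage genes after far-red light stood at 1.53 and 0.72 between the genotypes. Fitted on the arrays of the first day, elo3-6 differed from wild type in 13167 genes in darkness, 13782 after red light and 12038 after far-red light, and on the second day in 11431, 8008 and 9983. Light changed 7574 and 8186 genes in wild type and 7070 and 7867 in elo3-6 on the first day, and 4535, 5399, 2936 and 3692 on the second. The interactions had 1343 (red) and 1220 (far-red) calls on the first day, and 37 and 493 on the second. With the scan day as a block in a fit of all arrays, the red and far-red interactions had 1396 and 3091 calls, and with the slide as a block 719 and 1955. These fits count arrays rather than RNAs as replicates, and on data simulated for the red interaction the array-level fit made 431 false calls among 609, against 7 among 140 for the fit of RNAs. A slide held at most 4 arrays, too few to fit the groups within a slide.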

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

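The tests of a general compression of light responses and of shared probes were chosen after the result was seen, and the test without the noisy arrays was written before its result.

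In 23 of 351 groups of 4 experiments, 1 experiment lay far from the other 3, and chance marks about 1 in 20 such groups. Experiment 1 stood apart in far-red-treated elo3-6 against wild type for SESA5 (5.15), SESA3 (2.52), CRA1 (5.18), CCA1 (-1.21) and the seed storage list (2.55), and experiment 4 for AIR1 (1.69). After red light this comparison had AT3G05950 in experiment 1 (-1.50), RVE4 in experiment 4 (-0.79) and the light signalling list in experiment 3 (-0.25), and in darkness PHYA in experiment 3 (0.062). In wild type, F3H in experiment 1 (3.13) and the photosystem list in experiment 3 (0.71) stood apart under red light. Under far-red light these were LHCB2.1 (3.29), the light-harvesting list (2.15) and the light signalling list (1.16) in experiment 3, and LHY (0.64) and CHS (0.84) in experiment 1. In elo3-6 they were BBX31 in experiment 2 under red (4.69) and far-red light (4.36), LNK1 in experiment 4 under red light (2.84), and RTFL21 (-1.69) and the light-harvesting list (0.32) in experiment 1 under far-red light. The far-red interaction of XTH15 was 0.39 in experiment 3.

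The response to red light differed between the genotypes by the interaction term for 19 named genes. It was larger in elo3-6, or the fall smaller, for XTH15 (1.06), AT4G25250 (0.97), AT3G15570 (0.89), ELIP1 (0.88), HEC1 (0.86), XTH33 (0.84), RUP1 (0.59), MYB12 (0.59), HY5 (0.41) and SPA1 (0.40). It was smaller for BBX16 (-1.77), AT2G27420 (-1.33), MSRB6 (-1.25), AT1G48100 (-1.21), CGA1 (-1.20), CXE13 (-1.13), 4CL3 (-0.997), UGT89C1 (-0.70) and LHCB7 (-0.68). The lists that differed were light signalling (0.18), touch and wounding (0.19), light-harvesting (-0.54), photosystem (-0.21) and flavonoid genes (-0.17). Without experiment 2 every one of these genes except AT1G48100 and AT4G25250 lost the call, and 9 genes in all were called.

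Under far-red light the interaction passed for 24 named genes. It was positive for AT3G51750 (1.13), HAI3 (1.12), AT1G70640 (1.09), MAPKKK18 (1.08), EXO (1.01), CBF4 (0.98), XTH15 (0.88), HY5 (0.53) and SPA1 (0.38). It was negative for AT2G27420 (-1.76), LHCB2.2 (-1.60), AT1G60590 (-1.49), KAT5 (-1.49), AT5G42760 (-1.47), CXE13 (-1.44), LHCB2.1 (-1.35), LHCB3 (-1.29), 4CL3 (-1.27), UGT78D1 (-1.19), FBA1 (-1.06), UGT89C1 (-0.86), LHCB7 (-0.73), HEMA1 (-0.59) and RUP2 (-0.43). The lists that differed were touch and wounding (0.30), light signalling (0.14), light-harvesting (-0.66), photosystem (-0.32), flavonoid (-0.31), chlorophyll (-0.20) and seed reserve mobilisation genes (-0.12). With an estimated correlation the light signalling list under red light alone kept its call among the interaction lists (adjusted p = 0.013). With fry 1 list passed in the red interaction and 4 in the far-red interaction, against 5 and 7 with camera. Of 3616 tested probes that match no locus, 42 changed by 2-fold or more under red light in wild type, and their transcripts are not named in the sources used here.

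The light-harvesting genes rose less in elo3-6 than in wild type under far-red light, by a mean of -0.66, and under red light, by a mean of -0.54 with the same sign in 4 of 4 experiments. The explanations were tested on the far-red values alone. A general compression of light responses argues for an equal ratio of responses. However, the ratio of mutant to wild type was 0.553 (SD 0.24 over 4 experiments) for this list. For 397 responsive genes it was 0.904 (SD 0.12), and the list's ratio was lower in 4 of 4 experiments. The noisiest arrays of experiment 2 were not the whole cause, since experiments 1, 3 and 4, which hold none of them, had means of -0.79, -1.25 and -0.27. The mean without these arrays, -0.64, decides little, because they belong to 1 of the 4 experiments. Probes shared by the LHCB1 and LHCB2 families were not the whole cause, since 13 other members had a mean of -0.49. Why these genes responded less stays open, and no further explanation was tested. The far-red shift varied between experiments, from -1.25 to -0.27, and with an estimated correlation the list passed under neither far-red (adjusted p = 0.25) nor red light (adjusted p = 0.48).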

How the results depend on the processing

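The settings without the 2 noisiest arrays, with the scan day as a block and with a 2-fold change were chosen after the result was seen. Of 284 gene results run under the alternatives, nearly all of genes named in the text, 221 kept their side of the threshold under every alternative that gave a value, and of 67 list results 14 did. The filter for probes well above background in all 24 RNAs gave values for 275 of the gene results. No direction reversed for 283 of 284 genes and for 67 of 67 lists, the exception being the red interaction of CGA1, which was 0.13 with Agilent processed signals and with the deposited value table. With an estimated correlation 15 list results passed, and the other settings gave 62 to 92. With fry 57 of the 67 list results kept their call.

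Asking for a 2-fold change left 359, 368 and 328 genes between the genotypes in darkness, red and far-red light, 585 and 540 for red and far-red light in wild type, 472 and 407 in elo3-6, and 7 and 26 for the interactions, by construction. Median centring gave 4610 genes for far-red light in wild type, 3953 and 4263 for red and far-red light in elo3-6, 39 and 125 for the interactions, 3557 shared genes and an ELO3 change of -0.077 after red light (adjusted p = 0.44). The groups compared alone gave 3744 genes for far-red light in wild type, 3369 shared genes and 13 for the far-red interaction, and the direct arrays gave 4736 for far-red light in wild type. For the red and far-red interactions the counts on single-channel values were 120 and 278 with the replicate block and 69 and 173 without it. They were 30 and 49 with scaling between arrays, 1511 and 3227 in the array-level fit, 719 and 1955 with slides and 1396 and 3091 with scan days as blocks, and 6444 and 2714 from direct arrays. The last 4 settings treat arrays as replicates or omit the dye correction, and on simulated data for the red interaction 1951 of 2088 calls from direct arrays were false. For the other changes the cause was not tested.

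Leaving out each experiment gave 9 to 65 genes for the red interaction, 38 to 158 for the far-red interaction, 4337 to 6012 for far-red light in elo3-6, and an ELO3 change after red light of -0.20 to -0.14, never past the threshold. The other ranges were 11025 to 12670, 10774 to 12669 and 10330 to 11824 between the genotypes in darkness, red and far-red light, 5246 to 6250 and 5759 to 6849 for red and far-red light in wild type, 4541 to 5274 for red light in elo3-6, and 3961 to 4596 shared genes. Spots well above background made up 64.1% to 77.0% of a channel, which limits what can be said of dim transcripts.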

Other observations

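The tests of dye bias, curvature, exchanged labels and probe position were chosen after the result was seen, and the splits of the samples were planned.

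The lists that passed with camera in none of the 9 comparisons were cell wall expansion (16 measured), gibberellin and brassinosteroid metabolism (23), salicylate defence (11), jasmonate response (10), root markers (11) and stomatal lineage (7). Their smallest camera adjusted p values were 0.18, 0.56, 0.073, 0.089, 0.096 and 0.13. The matching list means were 0.18 for cell wall expansion after far-red light between the genotypes, 0.24 and 0.16 for the metabolism and jasmonate lists under far-red light in elo3-6, 0.19 for salicylate under red light in wild type, and -0.46 and -0.15 for root markers and the stomatal lineage in the far-red interaction. With fry, which does not compare a list with other genes, 4 of these lists passed in some comparisons, each upward. The smallest fry adjusted p was 1.5e-05 for gibberellin and brassinosteroid metabolism (far-red light in elo3-6), which passed for both lights in both genotypes. Its members did not rise as a body there. Under red light in elo3-6, 5 rose and 7 fell, and in the other cases 6 rose and 6 fell. The list medians lay between -0.036 and 0.020. For jasmonate response it was 1.2e-04 and for cell wall expansion 0.011, both after far-red light between the genotypes, and for salicylate defence 3.5e-04 (red light in wild type). Root markers (0.12) and the stomatal lineage (0.053) did not pass with fry either.

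For each of the 9 counts, 1 of 35 splits, the real one, gave as many genes. The splits were of the 8 RNAs compared, or of the 8 light responses for an interaction. These splits do not keep the pairing of RNAs by experiment, and the 8 splits that part every pair are too few for a share under 0.05. Between the genotypes the real counts were 13267, 13166 and 12638 in darkness, red and far-red light, and the highest of the other splits gave 14, 1 and 7116. For red and far-red light the counts were 7259 and 7623 in wild type against 496 and 3337, and 6247 and 6867 in elo3-6 against 2 and 1. The interactions had 124 and 333 genes against 0 and 1. The splits with 7116 and 3337 genes point to a structure of the samples: the first set the far-red elo3-6 RNA of experiment 1 with wild-type far-red RNAs of experiments 1, 2 and 4, and the second exchanged the dark wild-type RNA of experiment 1 with the far-red one of experiment 4. Among the 8 splits that part every pair, the highest other counts were 8 and 1065 in these comparisons, 0 for both interactions and 1 for the other comparisons.

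A large number of genes differed between elo3-6 and wild type in each light condition. Dye bias argues for opposite differences on direct arrays of opposite dye orientation, yet the uncorrected differences in darkness and after red light had a correlation of 0.82 across 20934 genes, which are not independent replicates. Curvature removed by loess was not the source of the directions of the called genes, since 99.8% of those called in darkness had the same sign under median centring. Their signs do not test how many genes differ. Median centring also raised the share of higher calls in darkness and after red light, as given above. A broad effect of the genotype may remain, most of it small, with a median change of 1.22-fold, and differences in growth or seed lots between the lines were not tested.

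ELO3 stood close to the wild-type level in elo3-6. An exchange of genotype labels within an experiment was argued against by the genotype differences of the 12 pairs, whose correlation across genes with the mean of the other 11 was at least 0.79. Whether the probe lies outside the part of the transcript that the insertion removes cannot be told apart from a transcript that is still made, because the position of the insertion is not given in the sources used here, and the far-red value of -0.29 fits either.

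Among genes that rose by 2-fold or more in wild type, the median ratio of the elo3-6 response to the wild-type response was 0.866 under red light (462 genes) and 0.821 under far-red light (466 genes). Genes chosen by their rise in elo3-6 were compared the other way round, as the wild-type response over the elo3-6 response. Their median ratio was 1.05 under red light (378 genes) and 1.03 under far-red light (363 genes). By the median the elo3-6 response was smaller under both choices, but the size of the difference depends on the genotype in which the genes were chosen. The differences in response of single experiments correlated across genes at 0.13 to 0.38 under red light and at -0.02 to 0.49 under far-red light.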
